A study of Mus musculus with 3 samples.

How the data were processed

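Spleen RNA and a universal mouse reference RNA were measured against each other on 3 two-colour arrays, per the labels with cRNA made by a single round of amplification, spleen in Cy5 and the reference in Cy3. The authors deposited 1 table of 16273 probes with a signed log ratio, or log fold, per array. The array type, image processing, background correction, normalization, log base and numerator are not given in the sources used here. The design had assumed log2 ratios. The deposited values do not settle the base: the largest value, 5.78, would be a 54.8-fold ratio in base 2, 322-fold in natural logs and 597130-fold in base 10, and the last exceeds the 65535 readings of a 16-bit scanner. Values were therefore tested as deposited, and a change of base alters folds and counts at a fold threshold, and not the tests against 0. The medians of probes measured on all 3 arrays were -0.028, -0.029 and -0.027. Whether the authors centred the arrays stays unknown, as does the scale.

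An exact 0 was read as no measurement. This choice was made on inspecting the table and the values of a few genes, ahead of any test: 930 probes had a value on 1 array and 0 on the others, with a median absolute value of 0.400 against 0.377 for probes measured on all 3 arrays, and 552 values lay within 0.01 of 0 beside 555 from 0.01 to 0.02 off it. On all 3 arrays 11086 probes were measured, 1142 on 2 arrays and 3115 on none. The probes at 0 include abundant genes such as Gapdh and both probes of B2m, so a gene at 0 is not to be read as unexpressed. No intensities were analysed here, so signal over background is unknown.

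Gene names came from the platform annotation supplied with the table, which lists 12397 probes, 12336 of them with 1 symbol and 61 with several, and leaves 3876 unnamed here. The gene IDs of 12228 probes were found in a RefSeq table of assembly GRCm38.p6, used for names only, and 0 symbols changed. Measured probes with 1 symbol (8591) were averaged into 6077 genes, of which 1491 had more than 1 probe. Probes of 139 of these genes (9.32%) were called in opposite directions.

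The samples formed 1 group, and the ratio of each probe or gene was tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept fit with moderated variance, two-sided, Benjamini-Hochberg adjusted p under 0.05). Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 31 lists, and 12 of the 43 lists had fewer members. The tests, the 43 lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The rule named the 12 highest and 12 lowest genes past the test with the same sign on all 3 arrays, passing over clone and predicted names, up to 4 members of each list with the largest absolute mean, and Actb and Gapdh. The handling of list synonyms was tightened after a first look at the results, which removed 1 globin gene from the erythroid list. Because both RNAs bear 1 product number each, the arrays may repeat the same extracts, in which case they would count as 1 replicate of the comparison.

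On simulated data with 6077 genes, limma recovered 1 of 50 genes shifted by 0.25, 43 of 50 shifted by 0.5 and 50 of 50 shifted by 1 or by 2, with 7 false calls. These errors were drawn independently between genes, and most genes were left unshifted. In the real data the deviations of neighbouring probe numbers correlated at 0.441 to 0.588 and 4270 genes passed. The recovery and false calls may therefore differ there. A list of 15 genes shifted by 0.5, 1 or 2 was recovered in 8, 20 and 20 of 20 rounds with the preset correlation and in 0 of 20 rounds at each size with an estimated correlation, which rests on few residual degrees of freedom here. There were 0 false calls among 620 lists with the preset correlation. In these rounds the real mean ratios were shuffled among genes, so the members of a list shared no error in their means. Such shared errors could give false calls in the real lists, and the 0 does not test for them.

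Other settings chosen at the same stage were centring, scaling and quantile normalization of the arrays, robust moderation, an adjusted p under 0.01, a test against a 1.5-fold change, an unmoderated one-sample test, probes measured on at least 2 arrays, other ways to combine the probes of a gene, camera with an estimated correlation, fry, leaving out each array and reading the values as natural logs. Scaling used the median absolute value directly, because the planned limma call gave no valid numbers on log ratios. Keeping 0 as a value and removing a trend along the probe numbers were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.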

Results

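Spleen RNA was compared with a common reference RNA on 3 two-colour arrays that form 1 group. On each array cRNA made from purchased mouse spleen total RNA carried the red dye Cy5, and cRNA made from a purchased universal mouse reference RNA, a pool of RNA from mouse cell lines, carried the green dye Cy3. The labels name the same product for each RNA on all 3 arrays, so the p-values measure only the spread between these arrays, which may be technical, and say nothing of other spleens or animals. The table holds 16273 probes with 1 log ratio per array, and its log base and numerator are not stated. A positive value is taken as likely higher in spleen, from the dye labels with the usual order of red over green and from the signs of gene lists fixed in advance, whose medians were 2.01 for B cells, 2.58 for T cells, 1.72 for erythroid cells, 4.66 for neutrophil granule genes and -1.32 for fibroblasts and extracellular matrix, with -0.05 for S phase. Those lists are therefore not independent evidence of the direction. The sample titles name the reference first and spleen second, which could mean the opposite order. No dye swap is labelled, so an effect of the dyes and a difference between the RNAs cannot be told apart. Folds are given for base 2 and for natural logs, since either may apply. Exactly 0 was deposited for 3940, 4356 and 4051 probes on arrays 1 to 3 (24.2%, 26.8% and 24.9%) and was read as no measurement, which left 11086 probes measured on all 3 arrays. The number of arrays limits the precision.

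The question the design poses is which genes differ in RNA level between spleen and the cell line pool, and how repeatable the ratios are between arrays. Positive ratios passed the gene test for 9 of 9 measured B cell genes, 5 of 6 T cell genes, 5 of 6 macrophage and monocyte genes, 8 of 9 erythroid genes, 3 of 3 neutrophil granule genes and 13 of 15 exocrine pancreas genes. Negative ratios passed for 11 of 15 extracellular matrix genes, 10 of 10 genes of a glycolysis and hypoxia list, 15 of 20 translation factor and tRNA synthetase genes and 28 of 40 oxidative phosphorylation genes, while 3 matrix genes, Igfbp3 at 3.54 among them, and 5 oxidative phosphorylation genes were positive. As lists, those large enough to test passed camera with its preset correlation and 0 passed with an estimated one. The estimated correlation also recovered a simulated shifted list in 0 of 20 rounds at each size, so its adjusted p cannot decide here. The highest mean log ratio of a named gene was 5.69 ± 0.083 (SD, n = 3) for Adamdec1, a disintegrin-like metalloprotease, and the lowest was -4.29 ± 0.28 (SD, n = 3) for Steap1, a membrane protein. Those sizes correspond to 51.8-fold and 19.6-fold if the base is 2, and to 297-fold and 73.0-fold if the logs are natural. With limma, 7576 of the 11086 probes (68.3%) passed an adjusted p of 0.05, of which 3580 were positive and 3996 negative. Which sign has more probes depends on the processing. The calls were 3803 positive and 3773 negative with each array centred on its median, which moves the split towards balance by construction. With 0 kept they were 2754 and 2727 (5481 of 16273 probes). With a trend along 5 probe numbers on either side removed they were 3354 and 3315. With 10, 20 and 40 probe numbers negative calls stayed more numerous (3686 and 3721, 3809 and 3885, 3861 and 3921). Keeping 0 and removing the trend were added after the data were seen. At least 2-fold ratios were called for 1544 probes in base 2 (860 positive, 684 negative) and for 2784 in natural logs (1394 positive, 1390 negative). After averaging the probes of each gene, 4270 of 6077 genes passed, 2017 of them positive and 2253 negative. The smallest mean ratio called for a probe was 0.17, so many calls are of small size, and limma's test against a 1.5-fold change in base 2 kept 2104 probes and 1208 genes. Without moderation of the variance, 4609 probes passed. Of 161 named genes, 43 lost their call against a 1.5-fold change, 22 without moderation and 8 at an adjusted p under 0.01, all named near the end.

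Across probes, Pearson's r between arrays was 0.956 for arrays 1 and 2, 0.969 for arrays 1 and 3 and 0.952 for arrays 2 and 3, with Spearman's rho of 0.907, 0.938 and 0.902. Probes are not independent replicates, so no p is given. The median SD of a probe over the 3 arrays was 0.119, and large ratios were more widely spaced than that: 128 called probes had a mean of 3 or more and 22 a mean of -3 or less. The deviations of an array from the mean of the 3 arrays were not independent between probes: neighbouring probe numbers correlated at 0.441 to 0.588 on the 3 arrays, whereas the mean ratios of neighbours correlated at 0.057. After the data were seen, a running median over 5, 10, 20 or 40 probe numbers on either side (windows 5 to 40) was subtracted. It was taken over the ratios themselves, the probe's own included, so it can remove real ratios as well as a trend. Separately, values of 0 were kept as measurements. The calls that ended are named with their genes. The genes that kept their call with a ratio moved by over 1.5 times are named at the end.

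**Figure D1:**
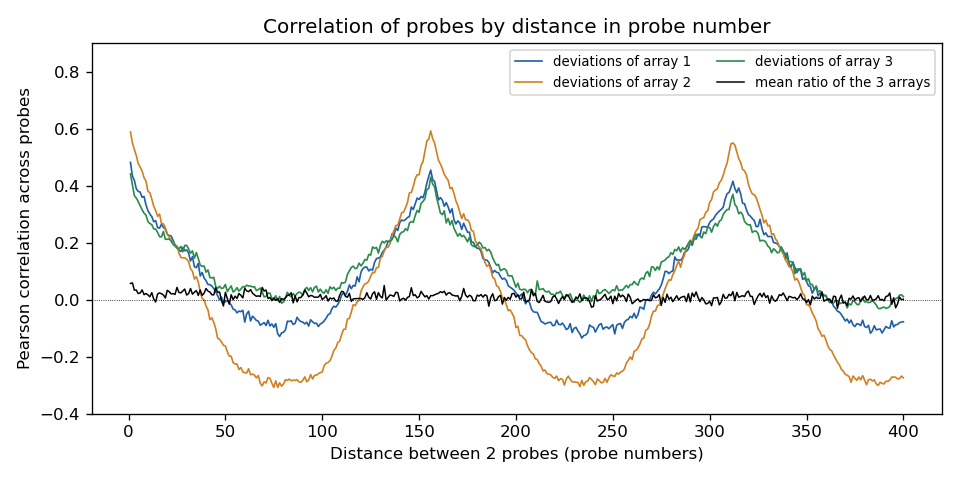
Pearson correlation across probes (vertical axis) between values a given distance apart in probe number (horizontal axis), for the deviations of each array from the mean of the 3 arrays and for the mean ratio itself. The mean correlation of the deviations is highest at a distance of 1 (0.503) and rises again to 0.492 at 156, where that of the mean ratio is 0.014.

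The 12 highest named genes were led, after Adamdec1, by Cd83, a marker of activated dendritic cells and B cells (5.52 ± 0.21, SD, n = 3), Ngp, a neutrophil granule protein (5.34 ± 0.27, SD, n = 3), and Reg2, a secreted protein of the pancreas (5.22 ± 0.13, SD, n = 3). Rnase6 had a mean log ratio of 4.93, Gp2, a zymogen granule protein, 4.80, the polymeric immunoglobulin receptor Pigr 4.79, Ms4a4c 4.78, the IgA heavy chain Igha 4.74, the chromatin organiser Satb1 4.69, the calgranulin S100a9 4.66 and the pancreatic lipase relative Pnliprp2 4.66 ± 0.60 (SD, n = 3). The same sign on the 3 arrays and a passed test were conditions of the rule, and the limma adjusted p of these 12 lay between 2.28e-08 and 1.33e-06. Among the 12 lowest, Zfpm2, a cofactor of GATA factors, had a mean of -4.07 ± 0.20 (SD, n = 3) and Plk2, a stress-responsive kinase, -3.67 ± 0.28 (SD, n = 3). Tnfrsf12a had -3.54, Ankrd1 -3.41, the mesenchymal transcription factor Twist2 -3.29, the neurotrophin Bdnf -3.25, the laminin chain Lamb1 -3.24, Syt13 -3.23, the meiotic gene Syce1 -3.14, Pxdn -3.11 and Emp1 -3.09. Most of these genes rest on 1 probe measured on all 3 arrays, except Tnfrsf12a and Twist2 with 3 each. Further probes of Satb1, Ankrd1 and Lamb1 held values of 0. With 0 kept the means of these genes were 2.35, -1.70 and -1.08.

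**Figure D2:**
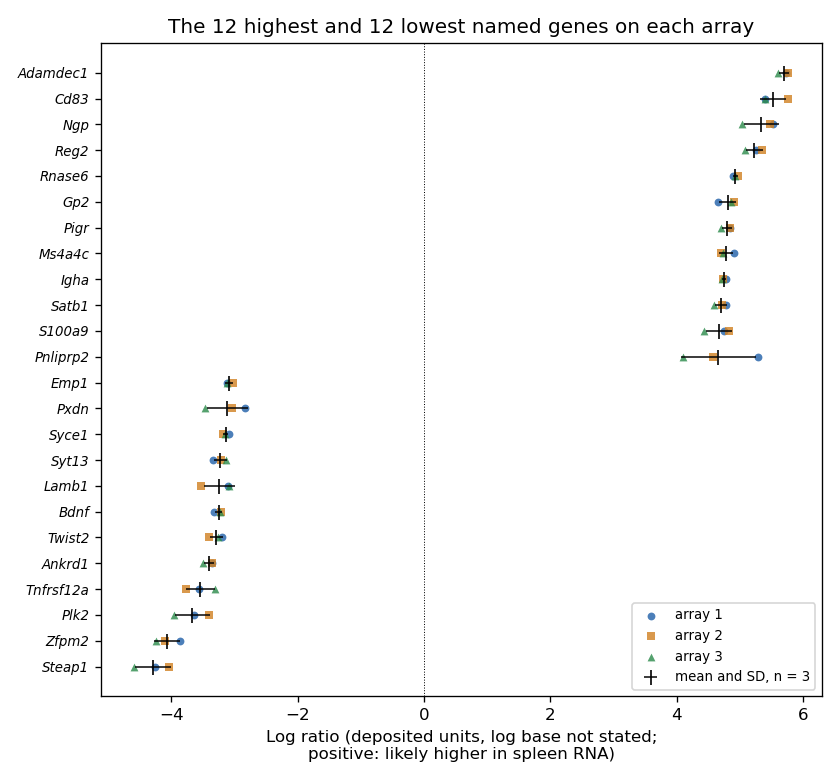
The 12 highest and 12 lowest named genes, with the log ratio in deposited units on the horizontal axis, 1 marker per array and a bar for the mean and SD of 3 arrays. The means run from -4.29 for Steap1 to 5.69 for Adamdec1, and the SD of Pnliprp2, 0.60, is wider than that of the other genes shown.

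Lymphocyte genes were mostly on the likely spleen side, which the signs of the B and T cell lists had helped to set. All 9 measured B cell genes were past the gene test and positive, with a median of 2.01. They included the complement receptor Cr2 (3.91 ± 0.26, SD, n = 3), the B cell surface protein Ms4a1 (3.53 ± 0.072, SD, n = 3), the BAFF receptor Tnfrsf13c (3.21) and Vpreb3 (2.72), and all 9 were also called adjusted over the list alone. Camera, which compares a list with all other genes, gave an adjusted p of 5.41e-05, and 0.414 was the adjusted p with an estimated correlation. Of the 6 T cell genes, 5 were positive and 1 was negative over all genes and adjusted over the list alone, with a median of 2.58. Satb1 (4.69), the co-receptors Cd8a (3.88) and Cd4 (2.24) and the T cell receptor zeta chain Cd247 (2.91) were positive, while Cd3d, a T cell receptor complex gene that lies outside the naming rule and was named after its value was seen, had a mean of -0.85. The T cell list gave a camera adjusted p of 0.00968, and the adjusted p with an estimated correlation was 0.483. That estimate was 0.51, against the preset 0.01, though on few residual degrees of freedom. If it holds, the camera p with the preset is too small for this list. The immunoglobulin and plasma cell list had 4 measured members, too few for the list test, and all 4 were positive with a median of 3.73: Igha 4.74, the light chain gene Iglv1 4.35, Ighm 3.11 and the transcription factor Xbp1 0.44. The call of Iglv1 ended with 0 kept (1.49, adjusted p = 0.0529), and that of Xbp1 ended with windows 5 and 10 (0.15 and 0.14, adjusted p = 0.109 and 0.101). Both measured NK and cytotoxic cell genes were positive, with log ratios of 2.91 for Nkg7 and 1.57 for the chemokine Xcl1 (0.73 with window 5). Probes of immunoglobulin genes can bind related family members, so single members are uncertain.

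Phagocyte, antigen presentation and signalling genes lay on the same side. Of 6 macrophage and monocyte genes 5 were positive and 1 did not pass, with a median of 1.26 (0.70 with 0 kept), including the iron exporter Slc40a1 (4.24 ± 0.22, SD, n = 3), Aif1 (3.58), the protease Ctss (1.35) and the Fc receptor chain Fcer1g (1.18). In the list test, camera gave an adjusted p of 0.00181, with an adjusted p of 0.414 with an estimated correlation. All 4 measured MHC class II and dendritic cell genes were positive, with a median of 2.19, and the log ratio was 5.52 for Cd83, 2.61 for H2-Oa, 1.77 for the integrin Itgax (1.12 with window 5) and 0.39 for the chemokine Ccl22. All 3 MHC class I and antigen processing genes were positive, with log ratios of 1.23 for Psme2, 0.97 for Tapbp and 0.59 for Psme1. The 5 interferon-induced genes were all positive with a median of 0.49, led by the GTPase Igtp (2.12) and Stat2 (1.47), followed by Iigp1 (0.49) and Bst2 (0.31). This list passed with a camera adjusted p of 0.0227, with an adjusted p of 0.483 with an estimated correlation, and did not pass when values of 0 were kept as measurements (adjusted p = 0.0825), nor did Bst2 itself (0.0879). Of 12 leukocyte signalling and adhesion genes, 9 were positive, 2 negative and 1 did not pass, with a median of 1.52 (0.87 with 0 kept). The actin regulator Coro1a had 2.62, the phosphatase Ptpn22 2.05, the adaptor Lcp2 2.02 and the GTPase Rac2 1.90. Against all other genes, camera gave an adjusted p of 0.0017, with an adjusted p of 0.414 with an estimated correlation. Each of these 5 lists had the same counts adjusted over the list alone. Cr2 was the 1 complement gene measured (3.91), and Cxcl14 the 1 gene of the lymphoid stroma and chemokine list (-0.30 ± 0.13, SD, n = 3), whose call ended with 0 kept (-0.15, adjusted p = 0.0647).

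Red cell and granulocyte genes were also mostly on the likely spleen side, which the signs of their lists had helped to set. Of 9 erythroid genes 8 were positive and 1 did not pass over all genes, 9 were positive adjusted over the list alone, and the median was 1.72 (0.86 with 0 kept). The alpha globin Hba-a1 had a mean log ratio of 3.22 ± 0.25 (SD, n = 3) over 11 probes, the beta globin Hbb-bs 2.64 ± 0.22 (SD, n = 3) over 14 probes, the red cell enzyme Bpgm 2.48 and the embryonic globin Hbb-y 1.84. Globin genes share sequence, so single members, the embryonic one in particular, are uncertain. Camera gave the erythroid list an adjusted p of 6.97e-05, with an adjusted p of 0.414 with an estimated correlation. All 3 neutrophil granule genes were positive, with log ratios of 5.34 for Ngp, 4.66 for S100a9 and 1.37 for the receptor Csf3r. Of 3 megakaryocyte and platelet genes 2 were positive, Clec1b at 3.85 and Treml1 at 2.14, and the thrombin receptor F2r was negative at -0.58. No mast cell and basophil gene was measured on all 3 arrays. Of 7 heme and iron handling genes 4 were positive, 2 negative and 1 did not pass, 4 and 3 adjusted over the list alone. They included Slc40a1 (4.24), the heme synthesis enzymes Fech (1.66) and Urod (1.55), and ceruloplasmin, Cp (-1.18), and the list did not pass (camera adjusted p = 0.355).

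Matrix genes were mostly on the likely reference side, which the sign of their list had helped to set. Of 15 fibroblast and extracellular matrix genes 11 were negative, 3 positive and 1 did not pass, over all genes and adjusted over the list alone, with a median of -1.32 (-0.63 with 0 kept). Lamb1 had -3.24, the matricellular protein Thbs2 -2.38 and the metalloproteinase inhibitor Timp3 -2.20 ± 0.58 (SD, n = 3), whereas the growth factor binding protein Igfbp3 was positive at 3.54 ± 0.12 (SD, n = 3). Camera gave an adjusted p of 0.0126, with an adjusted p of 0.414 with an estimated correlation. Of 8 epithelial genes 6 were negative and 2 did not pass, with Krt14 at -1.06, Ocln at -0.90, Cldn7 at -0.71 and Krt5 at -0.49, and the list did not pass (camera adjusted p = 0.148). With 0 kept, the calls of Krt5 (adjusted p = 0.0796) and of the endothelial gene Eng (0.0607) ended. Of 5 endothelial genes 3 were positive, 1 negative and 1 did not pass, with Esam at 2.97 ± 0.70 (SD, n = 3), Eng at 0.92, Flt1 at -0.23 and Ramp2 at 0.19 (camera adjusted p = 0.322). The call of Flt1 and that of Ramp2 ended without array 1 (adjusted p = 0.0537 and 0.125) and without array 3 (0.102 and 0.190), and that of Flt1 with window 5 (-0.096, adjusted p = 0.0777). Without array 3 the endothelial list passed (adjusted p = 0.0401). Of 5 smooth muscle genes the myosin Myh11 was positive at 2.27, Tpm1 negative at -0.78, and the other three did not pass, with Myl9 at 0.06 and Smtn at -0.06 (camera adjusted p = 0.773).

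**Figure D3:**
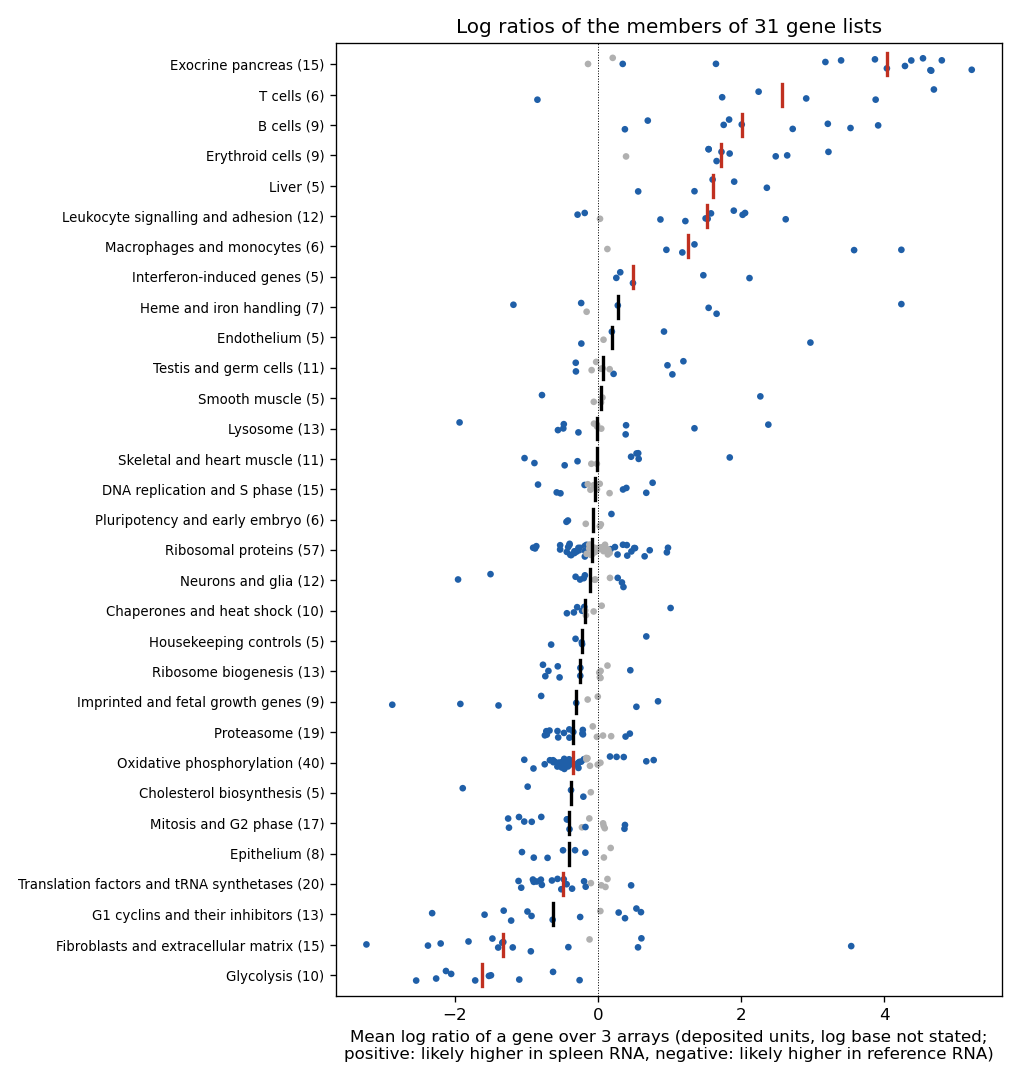
Members of the 31 tested gene lists, with the mean log ratio of each gene in deposited units on the horizontal axis, 1 point per gene (blue past the gene test, grey not), a bar at the list median (red where the list passed camera, black where it did not) and the number of measured members in brackets. The medians run from -1.62 for the list labelled glycolysis to 4.04 for exocrine pancreas.

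Genes of glycolysis and hypoxia, of oxidative phosphorylation and those of translation factors and tRNA synthetases were mostly negative, while ribosomal protein genes went both ways. All 10 genes of the list labelled glycolysis were negative, with a median of -1.62. Besides enzymes of the pathway this list holds the lactate transporter Slc16a3 and the hypoxia response genes Hif1a and Bnip3, a mitophagy gene (-2.54), and among the enzymes were Tpi1 (-2.26 ± 0.048, SD, n = 3), Hk2 (-2.13) and Ldhb (-2.05). In the list test, camera gave an adjusted p of 6.97e-05, with an adjusted p of 0.414 with an estimated correlation. Of 40 oxidative phosphorylation genes 28 were negative, 5 positive and 7 did not pass, with a median of -0.36, Ndufa7 at -1.03, Ndufc1 at -0.90, Atp5g2 at -0.75 and Ndufa1 at 0.78. Against all other genes, camera gave an adjusted p of 0.00249, with an adjusted p of 0.425 with an estimated correlation, and the call ended without array 3 (adjusted p = 0.0709). Of 20 translation factor and tRNA synthetase genes 15 were negative, 1 positive and 4 did not pass, with a median of -0.50 (-0.23 with 0 kept and -0.27 with window 5), led by Rars (-1.11), Nars (-1.07), Eif3c (-0.91) and Eprs (-0.90). Camera gave an adjusted p of 0.00518, with an adjusted p of 0.439 with an estimated correlation. These 3 lists had the same counts adjusted over the list alone. Among ribosomal protein genes, 13 of 57 were positive, 21 negative and 23 not past the test (12 and 17 adjusted over the list alone), with Rpl10a at 0.98, Rps27 at 0.96, Rpl22 at -0.91 and Rpl37 at -0.88 (camera adjusted p = 0.616). Of 13 ribosome biogenesis genes 7 were negative, 1 positive and 5 did not pass, with Utp20 at -0.77, Nolc1 at -0.74, Wdr12 at -0.69 and Ncl at -0.56 (camera adjusted p = 0.313). With 0 kept, the calls of Rpl37 (-0.47, adjusted p = 0.0705) and Ncl (0.0913) ended. Of 5 genes of the cholesterol synthesis list 4 were negative, with Cyp51 at -1.89, Fdft1 at -0.98, the sterol transporter Stard4 at -0.38 and Ebp at -0.21, and the list did not pass (camera adjusted p = 0.0563). With probes measured on at least 2 arrays it passed (adjusted p = 0.0192) and its median moved from -0.38 to -0.68. The call of Stard4 ended with windows 5 and 10 (-0.063 with each, adjusted p = 0.263 and 0.365). The call of Ebp ended without array 1 (adjusted p = 0.148), without array 3 (0.154) and with 0 kept (0.068), and its sign turned with each window (0.067 with window 20). Of 19 proteasome genes 13 were negative, 2 positive and 4 did not pass (3 positive adjusted over the list alone), with Psmd8 at -0.74, Psmb7 at -0.72, Psmc3 at -0.72 and Psmc6 at -0.68 (camera adjusted p = 0.0648). The proteasome list passed with probes on at least 2 arrays (adjusted p = 0.0435), with 0 kept (0.0315) and with windows 5 (0.0283) and 10 (0.0145). Of 10 chaperone genes 5 were negative, 1 positive and 4 did not pass, with the heat shock gene Hsph1 at 1.01, Cct8 at -0.44, Pdia6 at -0.34 and Hspb1 at -0.29 (camera adjusted p = 0.363). The call of Cct8 ended with 0 kept (-0.29, adjusted p = 0.0568), that of Pdia6 with 0 kept (0.0537) and window 5 (0.0956), and that of Hspb1 with window 10 (0.0515).

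Cell cycle genes went both ways. Of 17 genes of mitosis and G2 phase 10 were negative, 2 positive and 5 did not pass (11 negative adjusted over the list alone), with the kinase Cdk1 at -1.26 (-0.66 with window 5), Anln at -1.25, Racgap1 at -1.11 (-0.69 with window 5) and Cdc20 at -1.03, and the list did not pass (camera adjusted p = 0.0563). It passed with probes on at least 2 arrays (adjusted p = 0.0435) and with windows 10 (0.0343) and 40 (0.049), and the call of Cdc20 ended with 0 kept (-0.58, adjusted p = 0.068). Of 15 S phase genes 4 were positive, 4 negative and 7 did not pass, with Dbf4 at -0.84, Ccne2 at 0.76, Slbp at 0.67 and Dut at -0.58 (camera adjusted p = 0.97). Of 13 genes listed with the G1 cyclins and their inhibitors 8 were negative and 4 positive, with the inhibitor Cdkn1a at -2.32, the cyclin Ccnd1 at -1.59, Cdkn2c at -1.32 and Cdk6 at -1.21. That list did not pass on 3 arrays (camera adjusted p = 0.204) and passed without array 3 (0.037), and the call of Cdkn2c ended with 0 kept (-1.20, adjusted p = 0.0646). Of 9 imprinted and fetal growth genes 5 were negative and 2 positive, with Dlk1 at -2.88, Igf2bp1 at -1.92, Grb10 at -1.39 and Ndn at 0.84 (camera adjusted p = 0.23, and 0.037 without array 3). Of 6 pluripotency genes 2 were negative and 1 positive (2 and 0 adjusted over the list alone), with Dppa3 at -0.44, Sall4 at -0.42, Utf1 at 0.19 and Dppa5a at -0.17 (camera adjusted p = 0.616). The call of Utf1 ended without array 1 (adjusted p = 0.0698), 2 (0.0645) or 3 (0.297) and with 0 kept (0.0782). Both negative genes lost their call with some of the windows. Sall4 lost it with window 20 only (-0.13, adjusted p = 0.0709) and had -0.64 with window 5 (adjusted p = 0.000541). Dppa3 lost it with windows 5 and 10 (-0.25 and -0.11, adjusted p = 0.0522 and 0.0966). It kept the call with windows 20 and 40 (-0.19 and -0.24, adjusted p = 0.0155 and 0.0049). Dppa5a gained a call without array 3 (-0.26, adjusted p = 0.0456). Of 13 lysosomal genes 4 were positive and 5 negative, with Ctsc at 2.38, Cd63 at -1.94, Ctss at 1.35 and Asah1 at -0.56, and the list median was -0.015 with a mean of 0.056 (camera adjusted p = 0.97), turning positive when each array was centred on its median (0.013). Without array 3 the heme and iron list passed as well (adjusted p = 0.0276). Of 5 housekeeping controls 4 were negative and 1 positive, with Sdha at 0.67, Tubb5 at -0.66, Hprt at -0.31 and Actg1 at -0.23 (camera adjusted p = 0.472). The call of Hprt ended without array 2 (-0.35, adjusted p = 0.0579), without array 3 (-0.15, adjusted p = 0.245) and when each array was centred (-0.29, adjusted p = 0.0504). That of Actg1 ended without array 3 (adjusted p = 0.081). With 0 kept Hprt had no call (0.231), nor with windows 5, 20 and 40 (0.177, 0.121 and 0.31), and Actg1 had none with windows 5 and 10 (0.444 and 0.297). Gapdh was at 0 on all 3 arrays, and no probe is listed for Actb.

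Among lists for other tissues, exocrine pancreas had the most positive median, 4.04. Of its 15 measured genes 13 were positive and 2 did not pass, over all genes and adjusted over the list alone. Reg2 had a mean log ratio of 5.22, Gp2 4.80, Pnliprp2 4.66 and the ribonuclease Rnase1 4.64 ± 0.15 (SD, n = 3). For Reg2 this is 37.3-fold in base 2 or 185-fold in natural logs. In the list test, camera gave an adjusted p of 2.03e-07, with an adjusted p of 0.414 with an estimated correlation. Members of the Reg and protease families share sequence, so single members are uncertain. All 5 liver genes were positive with a median of 1.60 (0.88 with 0 kept), with the plasma proteins Apoh at 2.36, Ttr at 1.90, Apoc3 at 1.60 and Rbp4 at 1.35. Against all other genes, camera gave an adjusted p of 0.00265, with an adjusted p of 0.425 with an estimated correlation. Of 11 testis genes 4 were positive, 2 negative and 5 did not pass, with Star at 1.19, the sperm nuclear proteins Tnp1 at 1.04 and Prm1 at 0.97, and Hspa1l at -0.31 (camera adjusted p = 0.355). The call of Hspa1l ended with each of windows 5, 10, 20 and 40 (adjusted p = 0.0625, 0.261, 0.913 and 0.116), with a value of -0.0068 at window 20. Of 12 neuron and glia genes 6 were negative, 3 positive and 3 did not pass, with Stmn2 at -1.96, Ncam1 at -1.50, Nes at 0.35 and S100b at 0.33 (camera adjusted p = 0.496), and the call of S100b ended without array 1 (0.21, adjusted p = 0.0845) and with 0 kept (0.138), and that of Nes with 0 kept (0.16, adjusted p = 0.112) and window 10 (0.064, adjusted p = 0.307). Of 11 skeletal and heart muscle genes 5 were positive, 4 negative and 2 did not pass, with the transcription factor Mef2c at 1.84, Tnnt1 at -1.03, Myl1 at -0.89 and Ryr1 at 0.57. The muscle list had a median of -0.017 and a mean of 0.11, its camera direction was positive (adjusted p = 0.662), and its median turned positive when each array was centred on its median (0.011). The remaining tissue lists had few measured genes, with Aqp2 of kidney at 0.12 and not past the test, Aqp5 of lung at -0.75, and Lipe and Dgat2 of fat at -0.29 and 0.02. The call of Lipe ended without array 1 (adjusted p = 0.0743), with 0 kept (0.079) and with windows 5, 10 and 20 (0.342, 0.642 and 0.498), and Dgat2 did not pass.

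Stricter tests, and the test without moderation, ended the calls of some named genes, at the same mean ratios. Without moderation of the variance the calls that ended, with the adjusted p, were those of Xbp1 (0.0513), Ccl22 (0.0542), Bst2 (0.117), Cxcl14 (0.0912), Eng (0.0878), Ramp2 (0.0529), Krt5 (0.108), Slbp (0.0546), Dut (0.0522), Utf1 (0.106), Hspa1l (0.0616), Aqp5 (0.0517), Nes (0.0672), S100b (0.165), Lipe (0.107), Utp20 (0.0641), Ncl (0.12), Ebp (0.0953), Psmc3 (0.0626), Pdia6 (0.0797), Hspb1 (0.0616) and Hprt (0.256). Past an adjusted p of 0.05 but not of 0.01 were Flt1 (0.0118), Ramp2 (0.0282), Utf1 (0.0389), S100b (0.0135), Lipe (0.0101), Ebp (0.0275), Hprt (0.0352) and Actg1 (0.014). Not past limma's test against a 1.5-fold change in base 2 were Xbp1, Ccl22, Psme1, Iigp1, Bst2, Cxcl14, F2r, Eng, Flt1, Ramp2, Cldn7, Krt5, Ccne2, Slbp, Dut, Dppa3, Sall4, Utf1, Hspa1l, Aqp5, Nes, S100b, Ryr1, Lipe, Utp20, Nolc1, Wdr12, Ncl, Atp5g2, Stard4, Ebp, Psmd8, Psmb7, Psmc3, Psmc6, Cct8, Pdia6, Hspb1, Sdha, Tubb5, Hprt, Actg1 and Asah1.

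Several named genes kept their call and sign while their mean log ratio moved by over 1.5 times, up or down. With window 5 this held for 17 genes: Xcl1 (0.73), Ctss (0.79), Itgax (1.12), Ccl22 (0.66), Cxcl14 (-0.54), Cdk1 (-0.66), Racgap1 (-0.69), Cdkn2c (-0.83), Sall4 (-0.64), Utf1 (0.44), Ttr (1.21), Apoc3 (1.06), Rpl22 (-0.53), Wdr12 (-0.37), Atp5g2 (-0.49), Psmc3 (-1.13) and Cp (-0.68). With window 10 the 5 were Ctss (0.79), Ryr1 (0.28), Rpl22 (-0.54), Utp20 (-0.29) and Pdia6 (-0.22). The 7 with window 20 were Xbp1 (0.24), Flt1 (-0.15), Dppa3 (-0.19), Nes (0.20), Ryr1 (0.32), Wdr12 (-0.41) and Hspb1 (-0.45), and the 5 with window 40 were Dppa3 (-0.24), Nes (0.17), Ryr1 (0.32), Lipe (-0.19) and Hspb1 (-0.46). A running median holds the real ratios of the probe and its neighbours, so by construction a move with a window need not reflect a trend. Taking the probe with the largest ratio instead of the mean, which favours larger ratios by construction, moved 7: Psme1 (0.90), Cxcl14 (-0.48), Flt1 (-0.52), Dbf4 (-1.28), Utf1 (0.48), Grb10 (-2.16) and Sdha (1.11). Means shrink by construction with 0 kept, and 24 genes moved: Satb1 (2.35), Ankrd1 (-1.70), Lamb1 (-1.08), Cr2 (1.59), Tapbp (0.49), Hba-a1 (2.14), Hbb-y (0.61), Cldn7 (-0.35), Ccne2 (0.25), Racgap1 (-0.55), Ccnd1 (-0.79), Star (0.60), Ttr (0.95), Rbp4 (0.82), Aqp5 (-0.37), Rpl22 (-0.45), Wdr12 (-0.39), Eprs (-0.45), Bnip3 (-1.33), Ndufc1 (-0.45), Atp5g2 (-0.37), Sdha (0.34), Cp (-0.59) and Ctsc (1.19).

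Of 31 lists tested, 12 passed camera with its preset correlation, 8 positive and 4 negative. Among these 12 the estimated correlation ran from -0.14 for macrophages and monocytes to 0.51 for T cells. It was 0.30 for interferon-induced genes, 0.21 for exocrine pancreas and 0.16 for liver. These estimates are imprecise, but where the true correlation exceeds the preset 0.01, the camera p is too small. With an estimated correlation limma's camera called 0, with 3 lists at an unadjusted p under 0.05, and fry, which tests whether a list's genes move one way on balance, called 25. Where a list has no separate count, its counts adjusted over the list alone were the same as those over all genes tested.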

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

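Keeping values of 0 and removing the trend along the probe numbers, with each of its 4 windows, were chosen only after the results were seen. With 0 kept 5481 probes and 3263 genes (1601 positive, 1662 negative) passed, and with each array centred 4275 genes (2130 positive, 2145 negative). The window of 20 probe numbers on either side was picked after 4 windows had been tried: 5, 10, 20 and 40 gave 6669, 7407, 7694 and 7782 probes past the test. Over 18 alternatives for 161 named genes, 2754 values kept direction and side of the threshold, 128 lost the call, 1 gained it and 15 turned sign. Over 16 alternatives for 31 lists, 439 kept both, 14 lost the call, 25 gained it and 18 had a median of the other sign or of 0. Against a 1.5-fold change in base 2, limma called 2104 probes (1137 positive, 967 negative) and 1208 genes (626 positive, 582 negative). Without moderation it called 4609 probes (2365 positive, 2244 negative) and 2770 genes (1375 positive, 1395 negative). The test against a 1.5-fold change asks for larger differences by construction. Without moderation the SD of each probe or gene alone is used, with fewer degrees of freedom than the 6.72 for probes and 6.97 for genes of the moderated test. Fewer degrees of freedom raise the p at a given t by construction. How much of the loss of calls comes from this was not tested. Read as natural logs, 2784 probes were at least 2-fold. Camera with an estimated correlation, which recovered the simulated list in 0 rounds, called 0 lists and fry 25. The lowest correlation between arrays was 0.886 with 0 kept, and 0.966, 0.966 and 0.964 with windows of 20, 10 and 40. Leaving out 1 array gave 6287 to 7395 probes (2995 to 3484 positive, 3292 to 3911 negative), 3660 to 4151 genes, 12 to 15 lists and 1557 to 1564 probes at least 2-fold in base 2.

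No result that turned sign was called in the alternative, and among them only Ebp was called at first. With trend removal Ebp had 0.067 (window 20), 0.032 (5), 0.12 (10) and 0.027 (40), Dppa5a 0.025 (20), 0.11 (5) and 0.092 (10), Dgat2 -0.083 (20) and -0.0088 (10), Smtn 0.053 (5) and 0.011 (40), Aqp2 -0.027 (10) and Myl9 -0.032 (40). Among list medians, skeletal and heart muscle had 0.12 (20), 0.086 (5), 0.012 (10) and 0.036 (40), smooth muscle -0.065 (20), -0.022 (10) and -0.032 (40), neurons and glia 0.0046 (10) and lysosome 0.023 (40). Centring each array gave 0.011 for skeletal and heart muscle and 0.013 for lysosome, and probes on at least 2 arrays gave -0.0096 for smooth muscle. With 0 kept, the medians of smooth muscle, mitosis, pluripotency, skeletal and heart muscle, and heme and iron handling were 0. Leaving out 1 array gave Smtn between -0.14 and 0.021, Dgat2 between -0.036 and 0.069, and skeletal and heart muscle between -0.096 and 0.13. The cause was not tested.

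Robust moderation was not run for lists, since camera has no such option. Background correction, normalization within arrays, a filter on dim probes and a slide block were not run, as they need intensities, flags or slide numbers that were not analysed here, and signal over background therefore stays unknown. No paired analysis was possible because the arrays form 1 group.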

Other observations

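All tests of explanations in this part, their thresholds and the gene lists used here were chosen after the results were seen, except the exocrine pancreas list and the 7 other tissue lists, liver among them, which were fixed in advance. All 5 placental trophoblast genes were negative, with a median of -1.22. The larger values were those of the placental cathepsins Ctsm (-2.61), Ctsr (-1.47) and Ctsj (-1.22), on 1 or 2 probes each. Tpbpb had -0.33 over 15 probes and Tpbpa -0.30 over 24 probes. Of 7 immediate early genes 6 were negative and 1 positive, with a median of -2.19, among them Plk2 (-3.67), Fos (-2.60), Ier3 (-2.22), Id1 (-2.19) and Jun (-2.02). Of 7 genes of the membrane-spanning 4A family 5 were positive and 2 did not pass, with a median of 3.53, including Ms4a4c (4.78), Ms4a6c (4.46) and Ms4a4d (4.13). All 3 measured genes of a list of 16 chosen C-type lectins were positive, with log ratios of 4.14 for Clec4a2, 3.85 for Clec1b and 3.55 for Clec4b1, and the 1 Gimap GTPase measured, Gimap3, had 3.99 ± 0.34 (SD, n = 3). All 7 further acinar pancreas genes were positive, with a median of 2.60, from Serpini2 (3.42) and Reg3a (3.27) to Erp27 (0.81). Of 5 endocrine pancreas genes 2 were positive, Scg5 (2.27) and the insulin gene Ins2 (1.02 ± 0.29, SD, n = 3), 1 was negative, Gcg (-0.38), and 2 did not pass.

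The exocrine pancreas genes had a median log ratio of 4.04, and cross-hybridisation within the protease family is argued against as the whole cause by the 9 members that are not proteases, with a median of 4.29. The 43 genes of the other 7 tissue lists had a median of 0.040, and the highest, Apoh at 2.36, lay below the pancreas median. Tissue-restricted genes as such therefore did not give ratios of that size. That any such gene missing from the reference gives them stays open. Of the 43 genes 14 were past the test and negative, such as Stmn2 (-1.96) and Ncam1 (-1.50), so these are not missing from it. Which of the others are missing is unknown without intensities. RNA from abdominal tissue of every kind also stays open, since the stomach and liver genes differ. The 9 stomach genes had a median of 0.12 with an SD of 0.75. Of these, 4 were positive (Chia1 1.95, Tff2 1.04, Pgc 0.58 and Tff1 0.56) and 1 was negative (Gkn2 -0.67). The other 4 did not pass: Lipf 0.12 over 41 probes, Atp4b 0.0024 over 9 probes, Muc5ac 0.043 and Atp4a 0.032. All 5 liver genes were positive with a median of 1.60. Acinar pancreas RNA in the purchased spleen RNA stays open too. The 13 of 15 listed genes that were positive are the pattern itself and cannot count in its favour. They include Ctrb1 (4.54), Clps (4.29), Cela3b (4.04), Cpa1 (3.18) and Amy2a5 (1.65), while Ptf1a (0.20) and the acinar enzyme gene Cel (-0.14) did not pass. Transcription of these genes by spleen cells was not tested and stays open, as does an effect of the dyes.

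The deviation of each array from the mean of the 3 arrays followed the probe number. Neighbouring probe numbers correlated at 0.588 on the highest array and 0.441 on the lowest, against at most 0.028 over 100 shuffles of the positions, and the mean correlation peaked again at a distance of 156 probe numbers (0.492) and was 0.445 at 312. Co-regulated neighbours are argued against, since the mean ratios of neighbouring probes correlated at 0.057. A trend of the ratio across the surface of each array stays open, since these correlations are the pattern itself and the layout of the probes was not analysed here. Removing a running median took the median SD between arrays from 0.119 to 0.099. No other biological explanation was tested, as the design gives none within the group.

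Probes of 139 of 1491 genes were called in opposite directions. Gene names shifted against the probes throughout the table are argued against, since the median SD between probes of a gene was 0.214, below the 0.448 to 0.507 of 100 shuffles of the names. Wrong names for single probes were not tested and could remain.

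Turning the sign of 1 array at a time gives 4 choices of signs with the real one, which are too few for a share under 0.05. The real signs called 7576 probes and the highest of the others 0, so 1 of the 4 choices gave as many. Because the arrays correlated at 0.952 or more, turning 1 array sets its values against the others. The 0 follows from that, so no conclusion is drawn from this contrast.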
